A study of Mus musculus with 17 samples.

How the data were processed

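Gene expression was measured on 17 Affymetrix Mouse Gene 1.0 ST arrays. The samples were CD11b+ cells of 2 subsets, enriched with magnetic beads and sorted from pooled spleens of female BALB/c mice. Monocytic cells (Mo, high in Ly-6C and low in Ly-6G) and polymorphonuclear cells (PMN, low in Ly-6C and high in Ly-6G) came from naive mice and from mice injected under the skin with 100000 Her-2/CT26 colon carcinoma cells 3 or 6 weeks before. The labels give no batch, date or mouse, and do not say whether the numbered replicates of a group came from separate pools of spleens.

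The deposited values are intensities on a linear scale, which the authors made with RMA, a method that subtracts background, quantile normalizes and summarises the probes of each feature. No version or setting of RMA is stated. RMA gives log2 values and log2 values were assumed when the plan was written, but the deposited numbers run from 9.76 to 32095, so they were read as RMA values turned back to the linear scale and were put on the log2 scale again. The distinct values found on both arrays of a pair, at any feature, were counted. The median count was 942.5 for 2 Mo arrays (36 pairs), 251 for 2 PMN arrays (28 pairs) and 146 for arrays of different subsets (72 pairs). Upper quartiles ran from 254 to 298 in Mo arrays and from 183 to 202 in PMN arrays. The subsets were therefore treated as normalized apart. The planned comparisons of Mo with PMN levels were not made for that reason. Levels of sorting markers are given without a test. The tests of carryover between the gates compare Mo with PMN levels after quantile normalization over all 17 arrays. The test of B cell loss compares a ratio of intensities lost in Mo with that in PMN, on the deposited values. Contrasts of the change in Mo with the change in PMN were kept, since each change is a difference between arrays of 1 subset.

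The table held 35557 features. Of these, 21789 carried 1 gene symbol, 1621 carried several and 12147 carried none, and only the first kind were named. The Entrez number of 21698 features was found in the RefSeq annotation of GRCm38.p6, and 0 symbols had changed. For the 999 genes with several features, the feature with the highest mean was used, which left 19938 genes. Genes measured only by features of several genes, among them Ly6c1, Ly6c2, Isg15, Ccnb1 and Gapdh, are not named. Coordinates are those of the RefSeq gene on GRCm38.p6.

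One linear model with a mean for each of the 6 groups was fitted to all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with no filter on dim features. The 6 stage comparisons within a subset and the 3 differences between subsets of a stage change were tested two-sided. P-values were adjusted by Benjamini-Hochberg over the 19938 genes of each comparison, and a gene passed at an adjusted p below 0.05. All p-values in the report are from limma unless a set test is named. They measure the spread between these arrays, which may be technical where replicates share a pool, and the number of arrays, from 2 to 4 a group, limits the precision. Errors of changes are standard errors (SE) from the fit, and errors of levels are standard deviations (SD) over arrays.

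The groups, the comparisons, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. Of 30 gene lists, 17 cover pathways and cell programmes and 13 cover other cell types and sample quality. The list of mitochondrially encoded genes had 0 measured members and was not tested. The other 29 were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 29 lists of a comparison. Camera asks whether the genes of a list rank apart from the other genes. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other gene. Members of a list were also counted with p-values adjusted over the list alone. Genes were named by 4 rules: the 8 largest rises and the 8 largest falls among genes that passed and whose groups did not overlap; up to 4 members of each list; the 5 largest differences between the subsets each way; and a fixed set of suppression and sorting genes (Arg1, Nos2, Cybb, S100a8, S100a9, Il4ra, Cd274, Ly6g and Itgam). Predicted genes, small RNA genes, olfactory receptors and antigen receptor segments were skipped in the rules on largest changes.

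The pipeline was tested on simulated data, made from the mean of each gene in each subset plus independent normal noise with the spread of the fit. Of genes changed 1.5-fold, 76.12% were recovered with 3 arrays against 3 and 70.15% with 2 against 4, and all genes changed 2-fold or 4-fold were recovered. There were 6 and 9 false calls among 19938 genes in those comparisons and 0 in 3 comparisons with no change. The simulated noise had no structure shared between genes or arrays, so these counts do not measure false calls in the real arrays.

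The alternatives tried were to leave out dim genes, to fit each subset alone, to use an intensity trend with a robust prior, to weight arrays, to centre each array on its median, to repeat quantile normalization over the 17 arrays, to use the replicate number as a block, to raise dim values to the median of all values (a floor), to average the features of a gene, to test every feature, to require a 2-fold change, to estimate the correlation in camera, and to leave out each array in turn. The estimate of array weights did not converge and gave a weight of 50.8 to Mo 3 weeks replicate 2 and 0.123 to replicate 1, so its counts have little meaning.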

Results

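The study asked which factors make myeloid-derived suppressor cells more suppressive as tumours grow. Gene expression was measured in 9 Mo arrays, with 3 each from naive mice and from mice 3 and 6 weeks after injection of Her-2/CT26 cells, and in 8 PMN arrays, with 4, 2 and 2. Median intensity per array ran from 95.3 to 114 in Mo and from 81.0 to 95.9 in PMN arrays. The sorting marker Ly6g had a mean log2 intensity of 6.44 ± 0.97 (SD, n = 9) in Mo and 11.14 ± 1.17 (SD, n = 8) in PMN arrays. The monocyte receptor gene Ccr2 lay at 12.24 ± 0.13 and 6.30 ± 0.22, and the neutrophil receptor gene Cxcr2 at 5.91 and 12.55. Itgam, which encodes CD11b, lay at 11.35 ± 0.14 in Mo and 11.20 ± 0.44 in PMN. These levels were not tested against each other, because the subsets were normalized apart.

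**Figure D1:**
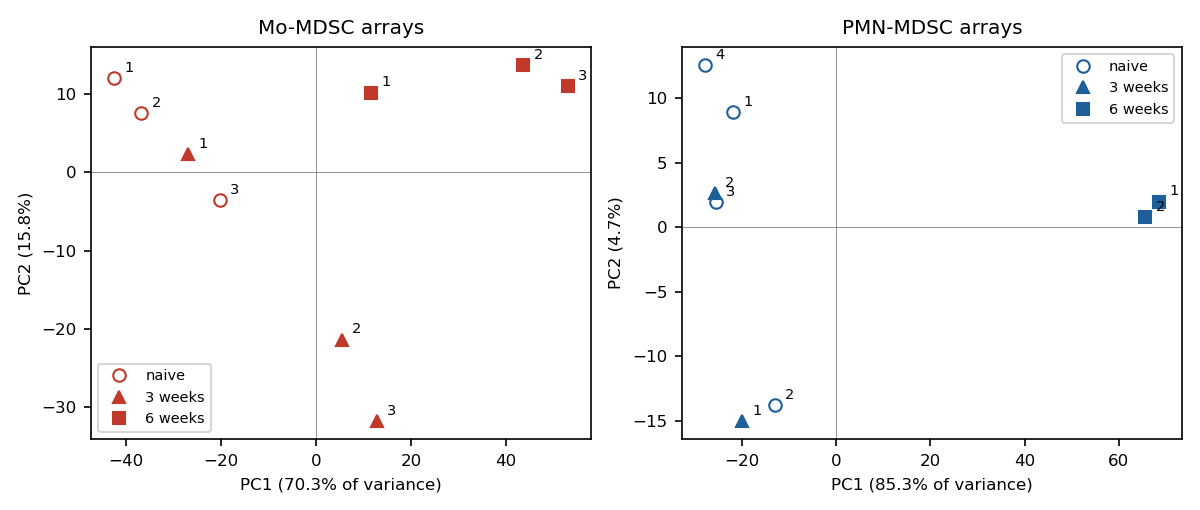
Each point is 1 array on the first 2 principal components of log2 intensity, computed for each subset alone. Colour marks the subset and marker shape the stage, with open points for naive arrays. Component 1 held 70.3% of the variance in Mo and 85.3% in PMN; the 2 PMN arrays of 6 weeks sit at 65.7 and 68.5, and the other 6 PMN arrays between -27.9 and -13.0.

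Along the first component of the Mo arrays, 6-week arrays lay at 11.5, 43.5 and 53.0 and naive arrays at -42.5, -36.7 and -20.2. The 3-week arrays lay between and beside them at -26.8 (replicate 1), 5.47 and 12.8, so that replicate 1 fell among the naive arrays. In PMN the 3-week arrays lay at -20.0 and -25.8, within the range of the naive arrays.

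The comparison of Mo cells at 3 weeks with naive mice asks what changes early. Vcan, which encodes the matrix proteoglycan versican, rose most, from a log2 intensity of 6.52 ± 0.33 to 9.19 ± 0.63 (SD, n = 3 each), a 6.36-fold increase (log2 2.67 ± 0.22 SE, adjusted p = 2.32e-05). It was measured by feature 10410931 (Entrez 13003, chromosome 13, 89655309 to 89743027). The chemokine receptor gene Ccr1 rose by 1.96 ± 0.25, the collagenase gene Mmp8 by 1.32 and Camk2d by 1.36. S100a8, a calcium-binding alarmin of neutrophils and monocytes, rose by 1.24 ± 0.28 (adjusted p = 0.0262), Chil3 by 1.12 and Lcn2 by 1.08. The genes that fell most were Apoe (-1.29 ± 0.23), which encodes a lipid carrier, the heat shock gene Hspa1a (-1.22 ± 0.14) and the macrophage lectin gene Siglec1 (-0.82). S100a8, given above, is 1 of the fixed suppression genes and passed. Of the others, Arg1 changed by -0.30 (adjusted p = 0.0766), Nos2 by -0.34 (0.114), Cybb by -0.03 (0.891), Cd274 by 0.24 (0.231) and Il4ra by 0.16 (0.212), and none of these passed.

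Among glycolysis and hypoxia genes, 6 of 25 rose and 0 fell at 3 weeks in Mo (12 and 1 when adjusted over the list alone), with Tpi1 at 0.69, Aldoa at 0.54 and Pgk1 at 0.54, and the list ranked high by camera (median 0.31, adjusted p = 5.22e-05). Fc and pattern recognition receptors had 6 of 25 higher (7 when adjusted over the list alone), with Clec4e at 1.32, Clec5a at 0.99 and Tlr4 at 0.86 (median 0.29, adjusted p = 0.000925). Specific and gelatinase granule genes had 6 of 22 higher (7 over the list alone), led by Mmp8, Chil3 and Lcn2, though the list median was 0.04 (adjusted p = 0.0144). Interferon-stimulated genes (1 of 26 higher, median 0.21, adjusted p = 0.0246), DNA replication genes (0 of 29, 0.19, 0.0246) and ribosomal protein genes (0 of 29, 0.18, 0.0144) ranked high with few or no single members past the test. Epithelial genes ranked low, with 2 of 12 lower (4 over the list alone, median -0.30, adjusted p = 0.00585). Each of these 7 list calls was lost with an estimated correlation (adjusted p = 0.669 with an estimated correlation for each). The lists of T cell suppression effectors (2 of 29 higher, median 0.04, adjusted p = 0.275), mitosis genes (0 of 29, 0.18, 0.0691) and B cell markers (0 of 18, -0.25, 0.091) did not pass. Nor did dissociation and immediate early genes, which cell handling can induce (1 of 17 lower, Hspa1a, list median -0.24, camera adjusted p = 0.0691).

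In this comparison 1036 genes were higher and 166 lower in limma, 86.19% higher, and 26 changed at least 2-fold. After centring each array on its median, which adds 0.136 to every Mo change at 3 weeks, the split was 1382 and 30; Vcan was then at 2.81 and Apoe at -1.15. The count of 1202 rested on single arrays: it was 18 without naive replicate 1, 17 without naive replicate 2, 16 without 3-week replicate 2 or 3, 2517 without naive replicate 3 and 8911 without 3-week replicate 1, and it was 2 when the Mo arrays were fitted alone. Vcan passed in each of these fits, and Ccr1, Camk2d, Mmp8, Hspa1a and Siglec1 in each but the last. The other genes named as risen or fallen did not pass without naive replicate 2 or 3-week replicate 2 or 3, nor, Clec4e apart, without naive replicate 1: adjusted p ran from 0.119 to 0.21 for S100a8, 0.0904 to 0.152 for Lcn2, 0.0794 to 0.0938 for Apoe, 0.181 to 0.321 for Chil3, 0.141 to 0.241 for Tpi1, 0.104 to 0.164 for Aldoa, 0.14 to 0.241 for Pgk1, 0.0934 to 0.122 for Clec4e, 0.13 to 0.216 for Clec5a and 0.14 to 0.249 for Tlr4. The interferon list lost its call without naive replicate 2 (0.106) or 3-week replicate 2 (0.0646) or 3 (0.118), and the replication list without naive replicate 2 (0.068) or 3-week replicate 2 (0.0523). With the floor the interferon (0.129), replication (0.308), specific granule (0.0716) and ribosomal (0.0738) lists did not pass. They did not pass with dim genes left out either (0.266, 0.266, 0.187 and 0.233). The first 3 did not pass after median centring (0.0523, 0.103 and 0.0828). The interferon (0.888) and ribosomal (0.599) lists did not after joint quantile normalization. With the floor S100a8, Chil3, Lcn2, Clec4e, Clec5a, Tlr4, Tpi1, Pgk1 and Apoe did not pass (0.0505 to 0.108). After joint quantile normalization Chil3 (0.0929), Tlr4 (0.0622), Tpi1 and Pgk1 (0.0706 each) did not.

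The comparison of Mo cells at 6 weeks with naive mice asks what marks the late stage. Vcan rose 28.5-fold, to a log2 intensity of 11.36 ± 0.02 (SD, n = 3; log2 change 4.83 ± 0.22 SE, adjusted p = 1.24e-09). Of 12 genes of the primary (azurophil) granules of early granulocytes 6 rose. Among these, Mpo, the gene of myeloperoxidase, rose 23.1-fold (4.53 ± 0.27), and the serine protease genes Ctsg and Elane rose by 4.24 ± 0.26 and 4.18 ± 0.26. Lcn2 rose 21.5-fold, S100a8 17.9-fold (4.16 ± 0.28) and the proliferation marker Mki67 9.69-fold (3.28 ± 0.35). MHC class II genes fell, with H2-Aa 13.3-fold lower (-3.73 ± 0.38, adjusted p = 2.9e-06), H2-Ea at -3.96 ± 0.42 and the invariant chain gene Cd74 at -3.34 ± 0.34. Mpo lies on chromosome 11 from 87793784 to 87804412 (feature 10380174, Entrez 17523) and H2-Ea on chromosome 17 from 34341952 to 34344645 (feature 10450161, Entrez 100504404).

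**Figure D2:**
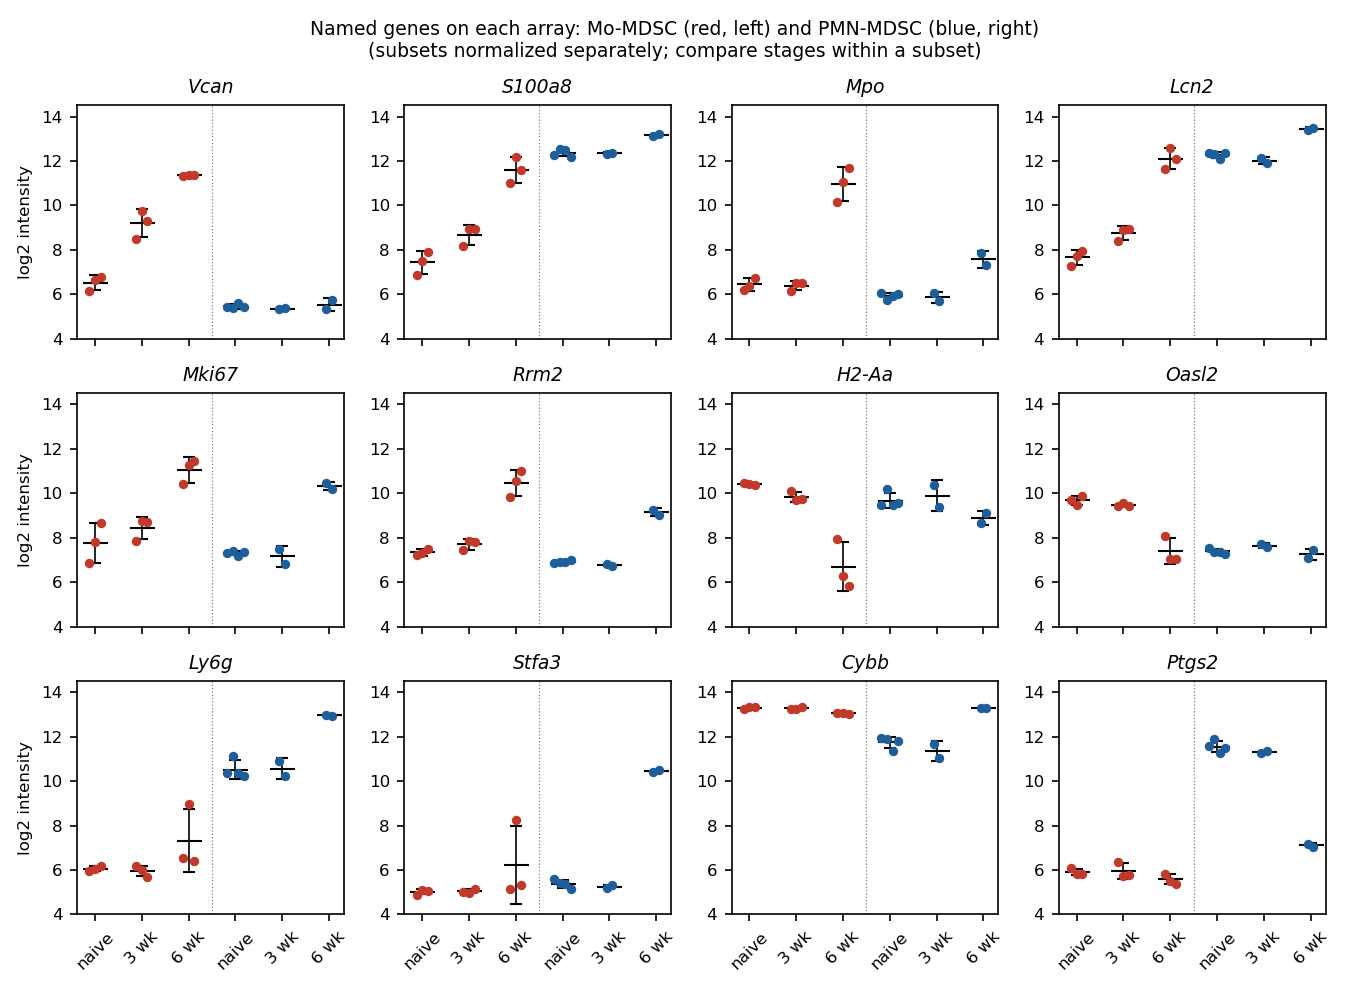
Log2 intensity of 12 genes in each of the 6 groups; points are arrays, and bars are the mean with its SD. Vcan rises from 6.52 in naive to 11.36 in 6-week Mo arrays, and Ptgs2 is at 11.56 in naive and 7.12 in 6-week PMN arrays.

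All 29 measured mitosis genes rose in Mo cells at 6 weeks, with Kif11 at 3.65, Nuf2 at 3.41 and Ccna2 at 3.33 (list median 2.65, adjusted p = 6.98e-31, and adjusted p = 0.183 with an estimated correlation). All 29 DNA replication genes rose too, with Rrm2 at 3.11, Mcm6 at 2.92 and Prim1 at 2.80 (1.81 with the floor; median 1.65, adjusted p = 6.17e-24, and 0.183 with an estimated correlation); both counts were also 29 when adjusted over the list alone. Of 12 azurophil granule genes 6 rose and 0 fell (7 and 0 over the list alone, median 0.92, adjusted p = 3.53e-06, and 0.183 with an estimated correlation). Of 22 specific and gelatinase granule genes 12 rose and 0 fell (12 over the list alone), with Ngp at 4.08, Chil3 at 3.95 and Mmp8 at 2.78 (median 0.73, adjusted p = 1.55e-06, and 0.261 with an estimated correlation). Mature neutrophil genes had 11 of 22 higher and 3 lower (12 and 4 over the list alone; median 0.67, adjusted p = 0.000288, and 0.361 with an estimated correlation), among them S100a9 at 3.88 and the decoy receptor gene Il1r2 at 3.78. Ly6g, the marker used to gate PMN cells, moved with these groups: its change was 1.24 ± 0.45 (adjusted p = 0.0333), and its level was 8.95 in 6-week replicate 2 against 6.56 and 6.42 in replicates 1 and 3. Replicate 2 was also the highest of the 3 for Stfa3 (8.26 against 5.13 and 5.31), Camp (9.89 against 7.94 and 7.79) and Ltf (11.03 against 9.05 and 8.72), but not for Mpo (10.17, 11.07 and 11.69 in replicates 1 to 3). The call of Ly6g ended with the floor (0.78, adjusted p = 0.319), without 6-week replicate 2 (0.42, 0.161) and without naive replicate 1 (0.0918) or 2 (0.0788).

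Of 26 interferon-stimulated genes 24 fell and 0 rose (24 over the list alone), with Ifi44l at -2.46, Oasl2 at -2.30 ± 0.20 and the interferon regulatory factor gene Irf7 at -1.86 (median -1.08, adjusted p = 3.51e-13, and adjusted p = 0.261 with an estimated correlation). Of 23 genes of MHC class II and the interferon-gamma response 14 fell and 1 rose (15 and 1 over the list alone), with H2-Ab1 at -2.92 and H2-Eb1 at -1.80 (median -0.60, adjusted p = 1.85e-05, and 0.261 with an estimated correlation). Markers of other cells that carry MHC class II fell beside them. Of 16 dendritic cell markers 11 fell and 1 rose (12 and 1 over the list alone), with Cd209a at -1.75 and Itgax at -1.12, while Flt3 rose by 1.32 (median -0.40, adjusted p = 0.00117, and 0.183 with an estimated correlation). That list median lay near the -0.325 of 1194 olfactory and vomeronasal receptor genes, which blood cells do not use. Of 18 B cell markers 11 fell and 0 rose (12 over the list alone; median -0.56, adjusted p = 0.00631, and 0.592 with an estimated correlation). The B cell gene Ms4a1 lay at 8.05 in naive replicate 1 against 6.28 and 6.29 in the other naive arrays, and its fall (-1.02, adjusted p = 0.0497) did not pass without naive replicate 1 (-0.43, 0.316) or 6-week replicate 2 (0.146) or 3 (0.143). Nor did it pass after median centring (0.11), joint quantile normalization (0.126) or the floor (-0.48, 0.422). H2-Aa was even across the naive arrays, at 10.47, 10.42 and 10.39. Of 19 T and NK cell markers 17 fell and 0 rose (18 over the list alone), with Gzma at -2.18, Ccl5 at -2.04 and Cd3g at -1.90 (median -0.76, adjusted p = 4.55e-09, and 0.183 with an estimated correlation). With the floor Gzma was at -1.30 and Cd3g at -1.04.

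Of 25 glycolysis and hypoxia genes 15 rose and 3 fell (16 and 3 over the list alone), with Ero1a at 1.46, Tpi1 at 1.37 and Pgam1 at 1.32 (median 0.56, adjusted p = 5e-06, and adjusted p = 0.261 with an estimated correlation). Genes of the unfolded protein response had 12 of 24 higher and 3 lower (the same over the list alone), led by the asparagine synthetase gene Asns at 1.57 (median 0.34, adjusted p = 0.00694, and 0.482 with an estimated correlation). Ribosomal protein genes had 13 of 29 higher and 1 lower (median 0.31, adjusted p = 3.34e-05, and 0.532 with an estimated correlation). Inflammatory genes linked to NF-kB had 3 of 28 higher and 12 lower, with Tnfaip3 at -0.91 and Il1b at -0.70 (median -0.23, adjusted p = 0.0394, and 0.564 with an estimated correlation); this call ended without 6-week replicate 1 (0.0611). Immediate early genes, which cell handling can induce, had 1 of 17 higher and 11 lower, with Atf3 and Fosb at -1.38 each (median -0.50, adjusted p = 0.004, and 0.564 with an estimated correlation). Each of the last 3 counts was the same over the list alone. Of 16 erythroid genes 3 rose (1 over the list alone; median 0.65, adjusted p = 0.00921, and 0.655 with an estimated correlation), a call that ended without naive replicate 3 (0.0536), 6-week replicate 1 (0.0815) or 6-week replicate 2 (0.213). Platelet genes had 7 of 11 lower (7 over the list alone; median -0.37, adjusted p = 0.0218, and 0.579 with an estimated correlation), and epithelial genes 5 of 12 lower (5 over the list alone; median -0.30, 0.0233, and 0.567). These medians lay near that of 1194 olfactory and vomeronasal receptor genes, which blood cells do not use (-0.325, with 593 lower and 0 higher). The median fall of the NF-kB list (-0.23) was no larger than that of the receptor genes.

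T cell suppression effectors did not shift as a list in Mo cells at 6 weeks: 8 of 29 rose and 6 fell (the same over the list alone), the median was -0.10, the mean 0.27 and the camera direction up (adjusted p = 0.614), and the median was 0.08 after median centring. Of the fixed suppression genes, S100a8 (4.16) and S100a9 (3.88) rose past the test. Arg1 changed by -0.17 (adjusted p = 0.183), Cybb by -0.26 (0.131), and Cd274 by -0.23 (0.182), none past the test. Il4ra rose by 0.22, with an adjusted p of 0.05 that lay below the threshold before rounding. It did not pass after joint quantile normalization (0.01, 0.918) or without naive replicate 1 (0.162) or 2 (0.143) or 6-week replicate 1 (0.0547), 2 (0.162) or 3 (0.0895). Nos2, the gene of inducible nitric oxide synthase, fell by 0.36 (adjusted p = 0.0427), near the median of -0.325 of the olfactory and vomeronasal receptor genes. It was at -0.18 after median centring (0.251) and after joint quantile normalization (0.285). That call was also lost without naive replicate 1 (0.134), naive replicate 2 (0.139) or 6-week replicate 1 (0.0505), 2 (0.0889) or 3 (0.121). Genes of STAT3 feedback (7 of 23 higher, 4 lower, adjusted p = 0.285), monocyte genes (5 of 22 and 8, 0.684), chemotactic receptors (3 of 17 and 5, 0.799), Fc and pattern receptors (7 of 25 and 6, 0.614), lipid genes (9 of 23 and 4, 0.34) and lysosome genes (4 of 24 and 4, 0.712) did not pass as lists. Among them the median and the test had unlike signs for Fc receptors (median -0.04, mean 0.15) and lysosome genes (-0.06 and 0.04), and the median and the mean for chemotactic receptors (-0.04 and 0.03).

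In this comparison 4341 genes were higher and 4863 lower in limma, 47.16% higher, and 643 and 135 of them changed at least 2-fold. Median centring adds 0.185 to every Mo change at 6 weeks and gave 5805 higher and 1379 lower genes, with Vcan at 5.02 and H2-Aa at -3.55; joint quantile normalization gave 3487 and 1754, and the floor 3648 and 1755. Without naive replicate 2 the count of 9204 was 5753, without naive replicate 1 it was 5063, and it was 5358 and 4475 without 6-week replicate 2 and 3. It was 5584 when the Mo arrays were fitted alone. After joint quantile normalization the unfolded protein response (0.274), ribosomal (0.182) and epithelial (0.0679) lists did not pass. The unfolded protein response list also did not with the floor (0.0501) or with dim genes left out (0.131), nor the erythroid list with dim genes left out (0.172). Camera called 18 lists with the preset and 0 with an estimated correlation, and fry called 17.

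**Figure D3:**
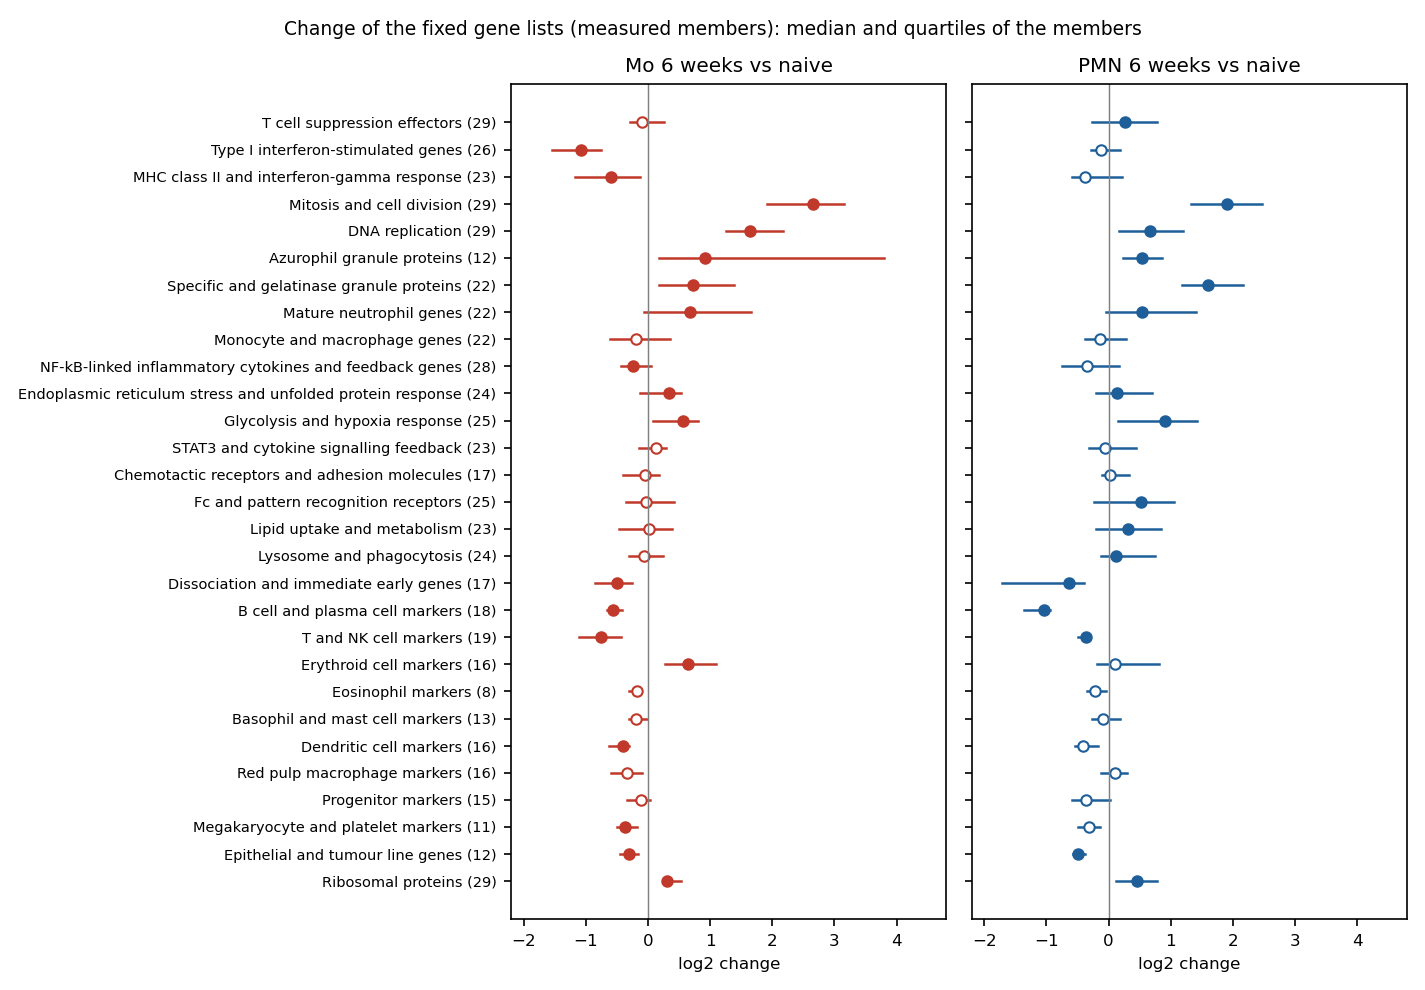
Median and quartiles of the log2 change of each list's members from naive to 6 weeks, in Mo and PMN cells; filled points passed camera with a preset correlation. Mitosis genes lie at medians of 2.65 and 1.91, and interferon-stimulated genes at -1.08 in Mo and -0.12 in PMN, where the median turns to 0.08 after median centring.

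The comparison of Mo cells at 6 weeks with 3 weeks asks what changes as the tumour grows. Mpo rose by 4.58 ± 0.27 (adjusted p = 3.95e-08, n = 3 each), the specific granule gene Ngp by 4.05, Ctsg by 3.95, Elane by 3.57, S100a9 by 3.31 and S100a8 by 2.92. H2-Ea fell by 3.35, H2-Aa by 3.15 ± 0.38 and Cd74 by 2.84. Arg1 changed by 0.14 (adjusted p = 0.548), Cybb by -0.24 and Cd274 by -0.48 (0.0545), and none of these passed. For Nos2 the change was -0.02 (0.947), and it was 0.29 (0.00287) with array weights.

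This comparison held the 6 list calls that remained with an estimated correlation, each at an adjusted p = 0.0197 with an estimated correlation. All 29 mitosis genes rose (29 over the list alone, median 2.44), 28 of 29 replication genes rose (29 over the list alone, 1.51) and 6 of 12 azurophil granule genes rose (8 over the list alone, 0.81), with 0 falling in each list. Of 26 interferon-stimulated genes 25 fell (26 over the list alone, median -1.26), with Ifi44l at -2.48, Oasl2 at -2.07 and Usp18 at -1.84. Of 23 genes of MHC class II and the interferon-gamma response 16 fell and 0 rose (18 and 1 over the list alone, median -0.69). Of 19 T and NK cell markers 13 fell (16 over the list alone, -0.66), with Gzma at -2.48 (-1.60 with the floor) and Ccl5 at -1.98. Dendritic cell markers moved beside the MHC class II genes, with 7 of 16 lower and 1 higher (8 and 1 over the list alone, median -0.32, adjusted p = 0.000124, and adjusted p = 0.0613 with an estimated correlation).

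Of 22 specific and gelatinase granule genes 8 rose (9 over the list alone, median 0.30, adjusted p = 1.91e-08, and adjusted p = 0.16 with an estimated correlation). Mature neutrophil genes had 5 of 22 higher and 2 lower (8 and 2 over the list alone, median 0.50, adjusted p = 4.74e-06, and 0.203 with an estimated correlation). Ly6g changed by 1.36 (adjusted p = 0.0824). Inflammatory genes linked to NF-kB had 8 of 28 lower and 0 higher (11 and 1 over the list alone), among them Il1b at -1.14 (median -0.15, adjusted p = 0.000374, and 0.212 with an estimated correlation). The olfactory and vomeronasal receptor genes had the same median (-0.15), with 2 of 1194 lower. Immediate early genes, which cell handling also induces, had 3 of 17 lower and 0 higher (3 and 1 over the list alone, median -0.24, adjusted p = 0.0129, and 0.542 with an estimated correlation), a call that ended without 3-week replicate 2 (0.168) or 6-week replicate 3 (0.119). Glycolysis and hypoxia genes had 6 of 25 higher and 2 lower (10 and 2 over the list alone, median 0.25, adjusted p = 0.000637, and 0.435 with an estimated correlation). Of the B cell markers 1 of 18 fell (2 over the list alone, median -0.37, adjusted p = 0.0138, and 0.56 with an estimated correlation), a call that ended with the floor (0.205) and without 3-week replicate 1 (-0.10, 0.446) or 6-week replicate 3 (0.117).

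Monocyte genes had 8 of 22 lower and 1 higher (10 and 4 over the list alone, median -0.26, adjusted p = 0.0101, and adjusted p = 0.542 with an estimated correlation), a call that ended without 3-week replicate 3 (0.0922). Fc and pattern receptors had 9 of 25 lower and 2 higher (9 and 4 over the list alone, median -0.27, adjusted p = 0.01, and 0.542 with an estimated correlation). From naive to 3 weeks this list had ranked high with the preset correlation only (adjusted p = 0.669 with an estimated correlation). The call of the fall from 3 to 6 weeks ended without 3-week replicate 2 (0.0531) or 3 (0.142) or 6-week replicate 3 (0.0517). Unfolded protein response genes had 3 of 24 higher and 1 lower (5 and 1 over the list alone, median 0.20, adjusted p = 0.0101, and 0.498 with an estimated correlation), and did not pass after joint quantile normalization (0.0995), with dim genes left out (0.0572) or without 3-week replicate 1 (0.164) or 6-week replicate 1 (0.0636) or 3 (0.0517). Ribosomal protein genes had 2 of 29 higher (2 over the list alone, median 0.14, adjusted p = 0.000374, and 0.542 with an estimated correlation), and did not pass after joint quantile normalization (0.246). Of 16 erythroid genes 1 rose (1 over the list alone, median 0.37, adjusted p = 0.00335, and 0.545 with an estimated correlation), a call that ended without 3-week replicate 3 (0.133) or 6-week replicate 1 (0.096) or 2 (-0.02, 0.612). Of 11 platelet genes 1 fell (1 over the list alone, median -0.12, adjusted p = 0.018, and 0.542 with an estimated correlation), a call that ended without 3-week replicate 1 (0.565) or 6-week replicate 3 (0.108).

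In limma 873 genes were higher and 624 lower in Mo at 6 weeks than at 3 weeks, 429 of them at least 2-fold. Without 3-week replicate 1 the majority turned, to 698 higher and 889 lower, and with array weights it was 3544 and 4265. The count of 1497 was 2803 without 6-week replicate 1 and 877 when the Mo arrays were fitted alone.

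In PMN cells at 3 weeks 0 of 19938 genes passed in limma against naive mice, or 9 with the floor (7 higher and 2 lower), and 374 had an unadjusted p below 0.05 where chance gives 997 (n = 2 and 4). Cybb, which encodes a subunit of the NADPH oxidase, changed by -0.40 ± 0.15 and the chemokine gene Cxcl2 by 0.57 ± 0.20, each with an adjusted p of 1. By camera, specific granule genes (median -0.13, adjusted p = 0.000861), red pulp macrophage markers (-0.23, 4.71e-06), lysosome genes (-0.07, 0.0199) and immediate early genes (-0.12, 0.027) ranked low and ribosomal protein genes high (0.24, 6.92e-14), with 0 members past the test in each list and 0 over the list alone. All 5 calls were lost with an estimated correlation (adjusted p = 0.933 with an estimated correlation). The red pulp call ended without naive replicate 2 (0.16) or 3-week replicate 2 (0.207), the lysosome call without naive replicate 2 (0.781) or 4 (0.0827) or 3-week replicate 2 (-0.011, 0.983), and the immediate early call without naive replicate 2 (-0.006, 0.967) or 3-week replicate 1 (0.351). The lysosome list did not pass with the floor (0.0604), nor the immediate early list after median centring (0.0559). The camera direction of the lysosome list turned without 3-week replicate 2, and that of the immediate early list without naive replicate 2.

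The comparison of PMN cells at 6 weeks with naive mice asks what marks the late stage in this subset. Stfa3, a stefin gene whose protein inhibits cysteine proteases, rose by 5.09 ± 0.54 (SE, adjusted p = 1e-06), from a log2 intensity of 5.38 ± 0.18 (SD, n = 4) to 10.47 ± 0.05 (SD, n = 2). Serpinb10 rose by 3.42 ± 0.24, Lta4h, the gene of an enzyme of leukotriene B4 synthesis, by 3.12 ± 0.23, and Mki67 8.04-fold. Ptgs2, which encodes the inducible cyclooxygenase COX-2, fell most, to 21.8-fold lower (-4.44 ± 0.18, adjusted p = 6.38e-11), from 11.56 ± 0.27 to 7.12 ± 0.09. The neutrophil chemoattractant gene Cxcl2 was 5.98-fold lower (-2.58 ± 0.20). Ly6g rose 5.4-fold (2.43 ± 0.48, adjusted p = 0.000443). Ptgs2 lies on chromosome 1 from 150100031 to 150108234 (feature 10350516, Entrez 19225) and Stfa3 on chromosome 16 from 36450537 to 36455392 (feature 10439299, Entrez 20863).

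All 29 mitosis genes rose in PMN cells at 6 weeks (29 over the list alone), with Nuf2 at 3.23, Top2a at 3.04 and Ccna2 at 2.93 (median 1.91, adjusted p = 1.86e-15, and adjusted p = 0.585 with an estimated correlation). Replication genes had 16 of 29 higher and 1 lower (the same over the list alone), with Rrm1 at 2.41 and Rrm2 at 2.22 (median 0.66, adjusted p = 3.64e-05, and 0.585 with an estimated correlation). Of 22 specific and gelatinase granule genes 20 rose and 0 fell (20 over the list alone), with Chil3 at 3.08, Olfm4 at 2.91 and the cathelicidin gene Camp at 2.57 (median 1.60, adjusted p = 1.94e-12, and 0.441 with an estimated correlation). Glycolysis and hypoxia genes had 17 of 25 higher and 1 lower (the same over the list alone), with Ero1a at 2.43, Hk3 at 1.85 and Pgam1 at 1.59 (median 0.91, adjusted p = 2.22e-07, and 0.585 with an estimated correlation). Of 12 azurophil granule genes 5 rose (5 over the list alone), with Mpo at 1.64 (0.98 with the floor; median 0.54, adjusted p = 0.0338, and 0.585 with an estimated correlation), a call that ended without 6-week replicate 1 (0.0526). Fc and pattern receptors had 14 of 25 higher and 5 lower (15 and 5 over the list alone), with Clec5a at 1.86 and Fcer1g at 1.45 (median 0.53, adjusted p = 0.0186, and 0.585 with an estimated correlation). Lipid genes had 10 of 23 higher and 2 lower (9 and 2 over the list alone), with the oxidized LDL receptor gene Olr1 at 2.36 (median 0.31, adjusted p = 0.0338, and 0.585 with an estimated correlation). Neither list passed after joint quantile normalization (0.189 and 0.0985).

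T cell suppression effectors had 13 of 29 higher and 6 lower in PMN cells at 6 weeks (14 and 7 over the list alone). Genes of the NADPH oxidase, which makes superoxide, rose: Ncf4 by 2.18, Cyba by 1.98, Ncf1 by 1.67 and Cybb by 1.55 ± 0.15. The list median was 0.27 (adjusted p = 0.0487, and adjusted p = 0.585 with an estimated correlation), and it was -0.04 after joint quantile normalization. The list did not pass without naive replicate 1 (0.0542), 3 (0.0682) or 4 (0.0702) or 6-week replicate 1 (0.0532) or 2 (0.0661). The IL-4 receptor gene Il4ra rose by 0.68 (0.29 after joint quantile normalization) and Itgam by 0.91. Arg1 fell by 0.44 (adjusted p = 0.00284) from a level of 5.79, below most genes, and it was at -0.25 (0.0624) after median centring and at 0 with the floor. Cd274, the gene of PD-L1, fell by 0.52 (0.0074), and was at -0.33 (0.116) after centring and at -0.41 (0.0999) without 6-week replicate 1. Nos2 fell by 0.41 (0.0226), and was at -0.22 (0.17) after centring and -0.17 (0.422) with the floor; it did not pass without naive replicate 3 (0.0612) or 6-week replicate 1 (0.0795) or 2 (0.114). S100a8 rose by 0.79 (0.0267) and S100a9 by 0.61 (0.0494). Neither call held after joint quantile normalization (0.65 and 0.37) or with the floor (adjusted p of 0.11 and 0.173): S100a8 had adjusted p from 0.0527 to 0.123 without naive replicate 1 or 4 or 6-week replicate 1 or 2, and S100a9 from 0.0621 to 0.185 without any 1 array of either group.

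Mature neutrophil genes had 13 of 22 higher and 4 lower (14 and 4 over the list alone, median 0.53, adjusted p = 0.0338, and adjusted p = 0.585 with an estimated correlation), and did not pass without naive replicate 4 (0.0534) or 6-week replicate 2 (0.0822). Unfolded protein response genes had 9 of 24 higher and 5 lower (the same over the list alone), with Asns at 2.51 (median 0.14, adjusted p = 0.0476, and 0.585 with an estimated correlation). Lysosome genes had 10 of 24 higher and 4 lower (the same over the list alone; median 0.12, adjusted p = 0.0407, and 0.596 with an estimated correlation). After joint quantile normalization the median of the unfolded protein response list was -0.04 and that of the lysosome list -0.16. Without naive replicate 1, naive replicate 3 or 6-week replicate 1, the unfolded protein response list had adjusted p = 0.0571, 0.071 and 0.0551 and the lysosome list 0.0571, 0.102 and 0.0551, and the former had 0.0543 without 6-week replicate 2. Ribosomal protein genes had 14 of 29 higher and 2 lower (the same over the list alone; median 0.46, adjusted p = 0.00215, and 0.585 with an estimated correlation), and the list did not pass after joint quantile normalization (0.496).

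Markers of B cells were lower in PMN cells at 6 weeks, with 17 of 18 lower (17 over the list alone), among them Cd79a at -1.88 and Fcer2a at -1.73 (median -1.04, adjusted p = 0.000178, and adjusted p = 0.585 with an estimated correlation). T and NK cell markers had 13 of 19 lower and 1 higher (the same over the list alone). The member that rose was the T cell gene Cd3d, at 1.62 (1.62 with the floor too), while Cd2 fell by 1.28. Their median was -0.37 (camera adjusted p = 0.0407, and 0.585 with an estimated correlation), where the olfactory and vomeronasal receptor genes had -0.36. The T and NK cell markers did not pass without naive replicate 1 (0.0571) or naive replicate 2 (0.0646). Beside these, Cd74 fell by 1.39 (adjusted p = 0.00332, and 0.0594 without 6-week replicate 1), and the MHC class II list had 11 of 23 lower and 3 higher (the same over the list alone; median -0.38, adjusted p = 0.49). Immediate early genes, which cell handling can induce, had 12 of 17 lower (12 over the list alone), with Nr4a1 at -2.30, Egr1 at -2.05 and Atf3 at -1.82 (median -0.63, adjusted p = 0.0108, and 0.585 with an estimated correlation). Epithelial genes had 11 of 12 lower (11 over the list alone; median -0.50, adjusted p = 0.0173, and 0.585 with an estimated correlation), where the olfactory and vomeronasal receptor genes had a median of -0.36. Inflammatory genes linked to NF-kB had 15 of 28 lower and 6 higher (the same over the list alone), with Ccl3 at -2.05 (median -0.35, adjusted p = 0.121). Interferon-stimulated genes had 5 of 26 higher and 5 lower (5 and 4 over the list alone; median -0.12, mean -0.07, camera direction up, adjusted p = 0.812).

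In this comparison 5075 genes were higher and 7972 lower in limma, 38.9% higher, and 1848 and 159 of them changed at least 2-fold. The median change of all genes was -0.18, and median centring, which adds 0.194, gave 5760 higher and 3507 lower, with Ptgs2 at -4.25, Cxcl2 at -2.39, Cybb at 1.75 and Ly6g at 2.63. Joint quantile normalization gave 4924 and 5527, and the floor 4315 and 2667. Of the 16 list calls 9 held with the floor, 8 with dim genes left out, 9 after joint quantile normalization and 13 after median centring. With the replicate block 11 held, and 13 with the PMN arrays fitted alone. With the floor the suppression (0.085), azurophil (0.325), mature neutrophil (0.155), unfolded protein response (0.285), Fc receptor (0.105), lipid (0.154) and lysosome (0.101) lists did not pass. With dim genes left out the same lists did not (0.155, 0.21, 0.401, 0.401, 0.163, 0.216 and 0.267), nor did the ribosomal list (0.0819). The suppression (0.496), mature neutrophil (0.392), unfolded protein response (0.688) and lysosome (0.786) lists also did not after joint quantile normalization. The first 3 of these did not after median centring (0.0607 each).

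The comparison of PMN cells at 6 weeks with 3 weeks asks what changes as the tumour grows (n = 2 each). Stfa3 rose by 5.22 ± 0.62, Chil3 by 3.90, Lta4h by 3.32 and Mki67 by 3.18, and the oxidase genes Ncf1 and Cybb rose by 2.09 and 1.95. Ptgs2 fell by 4.21 ± 0.21, Cxcl2 by 3.15, Ccl3 by 2.16 and Nr4a1 by 2.14. Mitosis genes had 28 of 29 higher (28 over the list alone, median 1.96, adjusted p = 8.96e-16, and adjusted p = 0.61 with an estimated correlation). Specific and gelatinase granule genes had 21 of 22 higher (21 over the list alone, median 1.94, adjusted p = 1.05e-13, and 0.339 with an estimated correlation). Glycolysis and hypoxia genes had 17 of 25 higher and 2 lower (the same over the list alone, median 0.89, adjusted p = 6.98e-07, and 0.61 with an estimated correlation). Immediate early genes, which cell handling can induce and which include Nr4a1, had 10 of 17 lower (11 over the list alone, median -0.77, adjusted p = 0.0314, and 0.61 with an estimated correlation). B cell markers had 17 of 18 lower (17 over the list alone, median -0.995, adjusted p = 0.000394, and 0.61 with an estimated correlation). T and NK cell markers had 13 of 19 lower and 1 higher (15 and 1 over the list alone, median -0.49, adjusted p = 0.0255, and 0.61 with an estimated correlation). The member that rose was Cd3d, at 1.66, while Cd2 fell by 1.17. Epithelial genes had 9 of 12 lower (10 over the list alone, median -0.43, adjusted p = 0.0314, and 0.61 with an estimated correlation), where the olfactory and vomeronasal receptor genes had a median of -0.34. Replication genes had 16 of 29 higher and 1 lower (the same over the list alone, median 0.62, adjusted p = 0.000326, and 0.61 with an estimated correlation). Azurophil granule genes had 5 of 12 higher (4 over the list alone, median 0.62, adjusted p = 0.033, and 0.61 with an estimated correlation). Neither passed with the floor (0.0794 and 0.378). Fc and pattern receptors (10 of 25 higher, 4 lower, median 0.43, adjusted p = 0.0255), unfolded protein response genes (10 of 24 and 4, 0.19, 0.0255), lysosome genes (10 of 24 and 2, 0.38, 0.0177) and lipid genes (9 of 23 and 4, 0.21, 0.0398) ranked high, each with an adjusted p = 0.61 with an estimated correlation and the same counts over the list alone. None of these 4 lists passed after joint quantile normalization (0.197, 0.373, 0.373 and 0.166) or with dim genes left out (0.207, 0.242, 0.152 and 0.242). Azurophil genes did not pass with dim genes left out (0.23). With the floor Fc receptors (0.153), unfolded protein response genes (0.15) and lipid genes (0.203) did not pass, and lipid genes did not after median centring (0.0684). The suppression list had 12 of 29 higher and 8 lower (the same over the list alone, median 0.23, adjusted p = 0.0565). Cd274 fell by 0.70 (adjusted p = 0.0037), and was at -0.49 (0.0518) after centring. In limma 4726 genes were higher and 6968 lower, 40.41% higher; the split was 5282 and 2438 after median centring, which adds 0.21, 4643 and 4363 after joint quantile normalization and 3973 and 2371 with the floor. The count of 11694 was 7627 without 3-week replicate 2.

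The contrast of the change in Mo with the change in PMN asks where the subsets respond unlike each other. From naive to 6 weeks, Vcan changed by 4.83 in Mo and 0.08 in PMN, a difference of 4.76 ± 0.33 (adjusted p = 1.76e-07), and Ptgs2 by -0.33 and -4.44, a difference of 4.11 ± 0.25 (3.84e-08). The azurophil genes Ctsg (4.24 and 0.45) and Elane (4.18 and 0.63) rose more in Mo, and Stfa3 (1.21 and 5.09) and Serpinb10 (-0.21 and 3.42) more in PMN. H2-Aa fell more in Mo (-3.73 and -0.78, difference -2.95). Interferon-stimulated genes had a lower change in Mo than in PMN for 19 of 26 members (21 over the list alone, median difference -1.13, adjusted p = 4.77e-14, and adjusted p = 0.599 with an estimated correlation). Most of this list did not fall past the test in PMN. Replication genes had a higher change in Mo than in PMN for 21 of 29 (27 over the list alone, median 0.97, adjusted p = 9.58e-12, and 0.599 with an estimated correlation). Of specific and gelatinase granule genes 9 of 22 changed less in Mo and 3 more (the same over the list alone, median -0.78, adjusted p = 0.000224, and 0.599 with an estimated correlation). In limma 1290 genes had a higher and 2197 a lower change in Mo, and that count of 3487 was 2145 and 2098 without PMN 6-week replicate 1 and 2.

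Between naive and 3 weeks, Vcan was the 1 gene whose change differed (2.77 ± 0.33, adjusted p = 0.00334); it did not pass without PMN 3-week replicate 1 (0.0775) or 2 (0.053), and the count was 9 without Mo naive replicate 3 and 3242 without Mo 3-week replicate 1. Between 3 and 6 weeks 2373 genes had a higher and 3445 a lower change in Mo, or 767 and 3500 after median centring. Cxcl2 changed by 0.11 in Mo and -3.15 in PMN (difference 3.26), and the acute phase gene Saa3 by 3.12 and -0.11 (3.23). The count of 5818 was 3641 without PMN 3-week replicate 2 and 9334 without Mo 3-week replicate 1.

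**Figure D4:**
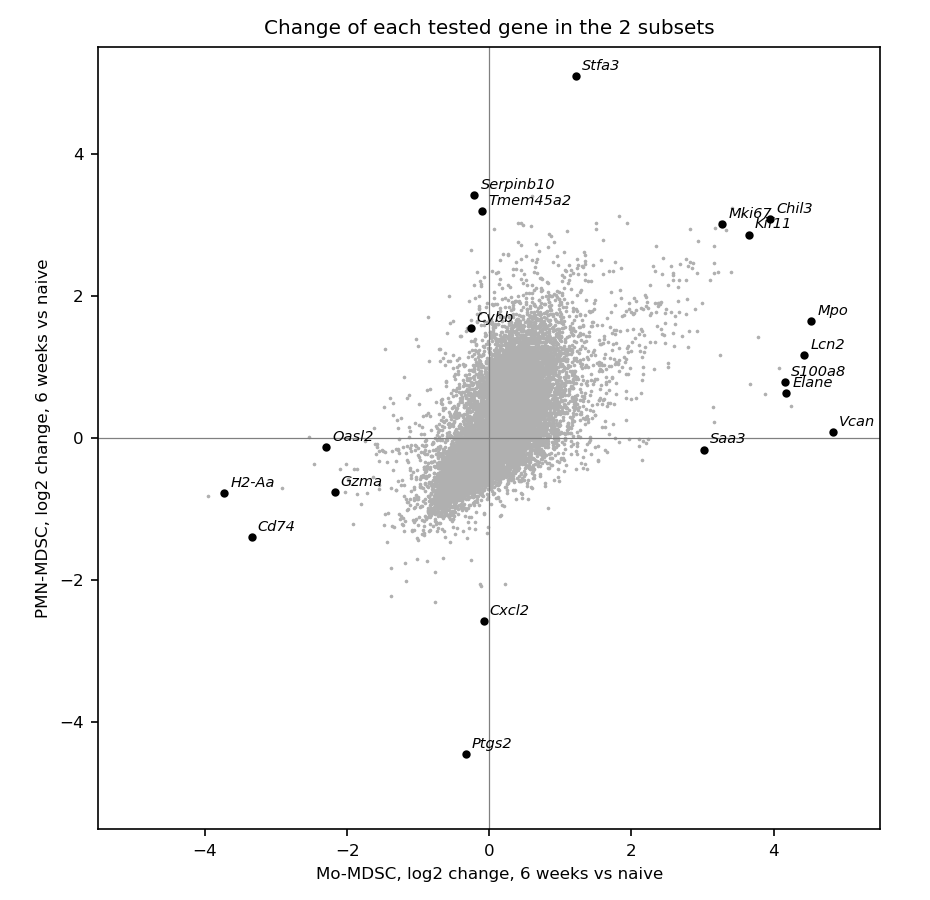
Each point is a gene, with its log2 change from naive to 6 weeks in Mo on the horizontal and in PMN on the vertical axis. Vcan lies at 4.83 and 0.08, Stfa3 at 1.21 and 5.09, and Ptgs2 at -0.33 and -4.44.

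Across the 19938 genes, which are not independent replicates, the changes from naive to 6 weeks in Mo and PMN had a Pearson r of 0.686 and a Spearman rho of 0.751. Of the genes past the test in both subsets, 2907 were higher in both (1105 by independent draws), 3755 lower in both (1944.4) and 278 opposite. The shared falls may hold a shift of dim features. Of 1194 olfactory and vomeronasal receptor genes, 593 were lower in Mo and 684 in PMN, with 0 higher in each subset. With the floor the genes lower were 1755 in Mo and 2667 in PMN, and r was 0.598. Mki67 (3.28 and 3.01) and Chil3 (3.95 and 3.08) rose in both. Within Mo, 945 genes were higher at both 3 and 6 weeks than in naive mice, 155 lower at both and 5 opposite. Both changes share the naive arrays. The r of these changes was 0.742. In 100 simulations with no stage effect r was 0.5, which the design fixes and which is not a share of 0.742. The covariance of the changes was 0.1009, against 0.0086 in the simulations. Independent noise in the shared naive arrays thus gives little of it, and noise shared across genes was not simulated.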

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

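The test of 6 granule genes (Chil3, Hp, Fcnb, Mmp8, Ngp and Lcn2) and the share of signal kept above the receptors were chosen after the result was seen; the other tests in this part were chosen before.

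In Mo cells at 6 weeks 6 of 12 azurophil and 12 of 22 specific granule genes were higher than in naive mice and 0 lower (adjusted p = 0.183 and 0.261 for the lists by camera with an estimated correlation). The median difference of the Mo from the PMN change was 0.69 for the azurophil list and -0.78 for the specific list (adjusted p = 0.599 with an estimated correlation for each). The specific list held members that differed either way. A carryover of cells from the PMN gate is argued against as the source of the azurophil part: 5 of its 6 risen genes lay over 1 log2 unit higher in Mo than in PMN arrays at 6 weeks after joint quantile normalization (10.53 and 7.79 for Mpo, 10.19 and 6.57 for Ctsg), and a mixture cannot exceed its source. For the specific and gelatinase list it stays open. The median share of PMN RNA needed by 33 other genes abundant in PMN and low in naive Mo arrays was 0.178 of that needed by 12 granule genes. The upper quartile of the others (8.16%) reached 0.415 of the granule median, above the bound set. The 12 granule genes were taken because they had risen in Mo, which favours high shares, and the 33 others were not. The 0.178 therefore decides nothing. Camp (3.76%), Ltf (5.32%) and Olfm4 (1.86%) need less than that quartile, Slpi (12.9%), Arg2 (13.9%) and Anxa1 (15.4%) need more, and the other 6 need 24 to 66.5%, at least 2.93 times it, which decides nothing since they were picked for their high shares. A greater share of granulocyte or monocyte precursors in the Mo gate and a change within the same cells both remain candidate explanations, and these arrays cannot separate them.

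By camera, the list of MHC class II and interferon-gamma response genes ranked low for the Mo minus PMN change at 6 weeks (median difference -0.37, adjusted p = 0.000145, and adjusted p = 0.599 with an estimated correlation). Changes in Mo and PMN were -3.73 and -0.78 for H2-Aa, -2.92 and -0.7 for H2-Ab1, -1.8 and -0.92 for H2-Eb1, and -3.34 and -1.39 for Cd74. Loss of B cells as the whole cause of the fall of these 4 genes in Mo is argued against. Together they lost 4486 intensity units in Mo for 306 lost by Cd79a, Cd79b and Ms4a1. In PMN they lost 1682 for 1070, a ratio of ratios of 9.38 and at least 7.16 without any 1 array. Each ratio was taken within 1 subset on the deposited values, with no joint normalization. Loss of dendritic cells stays open: their 4 markers had a median change 2.3 log2 units above that of the MHC class II genes, which met the bound set, but that bound took no account of background or of other cells that express a marker. The signal kept was taken above the level of olfactory and vomeronasal receptors, which blood cells do not use. Cd209a kept 21.9% of its naive signal, within the 6.98 to 26.9% of the MHC class II genes. Itgax (43.8%), Bst2 (67.4%) and Tcf4 (86.5%), which monocytes also express, kept more. Whether Cd209a came from dendritic cells alone in these arrays was not tested. A lower expression in the Mo cells themselves, as tumours grow, may be the cause and was not tested.

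The change itself was tested for a difference between the subsets, and 1 gene passed from naive to 3 weeks (Vcan, 2.77), 3487 passed from naive to 6 weeks and 5818 from 3 to 6 weeks. From naive to 6 weeks, the difference of log2 changes, Mo minus PMN, was 4.76 for Vcan, 4.11 for Ptgs2, 3.79 for Ctsg, 3.55 for Elane and 3.37 for S100a8. At the other end it was -2.95 for H2-Aa, -3.14 for H2-Ea, -3.30 for Tmem45a2, -3.63 for Serpinb10 and -3.87 for Stfa3. From 3 to 6 weeks it was 3.83 for Ptgs2, 3.39 for Ctsg, 3.26 for Cxcl2, 3.23 for Saa3 and 2.87 for Mpo, and -3.02 for Stfa2, -3.02 for Aldh2, -3.24 for Tmem45a2, -4.04 for Stfa3 and -4.23 for Serpinb10.

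Of the fixed lists, 14 differed from naive to 6 weeks by camera with the preset correlation, and 0 did with an estimated one (smallest adjusted p = 0.599 with an estimated correlation). Median differences were positive for mitosis (0.47), replication (0.97), azurophil granule (0.69) and B cell (0.64) lists. They were negative for the lists of interferon-stimulated genes (-1.13), MHC class II and the interferon-gamma response (-0.37), specific granules (-0.78), glycolysis (-0.23), chemotactic receptors (-0.18), Fc receptors (-0.33), lipid genes (-0.33), lysosome genes (-0.30), T and NK cells (-0.35) and red pulp macrophages (-0.56). With the floor 8 of the 14 held, and with dim genes left out 9 held. After joint quantile normalization 7 of the 14 held: mitosis (0.0763), azurophil granules (0.0509), chemotactic receptors (0.107), Fc receptors (0.0509), lysosome genes (0.266), T and NK cells (0.0509) and red pulp macrophages (0.266) did not pass. Without 1 array, the adjusted p of chemotactic receptors was 0.0599 to 0.0968 (Mo naive 3, Mo 6 weeks 3, PMN naive 3 or 4, PMN 6 weeks 2) and that of Fc receptors 0.0625 to 0.0795 (Mo naive 3, Mo 6 weeks 3, PMN 6 weeks 2). It was 0.051 to 0.113 for lysosome genes (Mo naive 1 or 3, Mo 6 weeks 2 or 3, PMN naive 1 or 3, PMN 6 weeks 1 or 2) and 0.0618 to 0.103 for red pulp macrophages (Mo naive 1, Mo 6 weeks 3, PMN naive 1 or 3, PMN 6 weeks 1).

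In the 4 naive PMN arrays, 9 of 141 genes had 1 array far from the others, where chance gives about 1 in 20 genes, or 7. As a share of the whole range, the gap was 0.832 for Cyba, 0.855 for Dnajb9, 0.833 for Ly6g, 0.835 for Nr4a1, 0.83 for Olfm4 and 0.911 for Serpinb10 (each highest in replicate 2). It was 0.906 for Krt8 (lowest in replicate 2), 0.93 for Rrm2 (highest in replicate 4) and 0.862 for Ifit3 (lowest in replicate 4).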

How the results depend on the processing

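The alternatives were chosen before the data were examined. Of 480 stage changes of named genes past the threshold, 475 kept direction and threshold with a replicate block or an intensity trend and 477 with features averaged. The number was 428 after joint quantile normalization, 425 after median centring, 406 with each subset fitted alone and 374 with the floor. All 480 did with array weights, which shows no stability, since that estimate did not converge and called 15177 genes for Mo 3 weeks. Without 1 array in turn 2255 of 2646 values did, and 0 reversed. Of 78 list calls, 6 held with an estimated correlation, 60 after joint quantile normalization, 59 with the floor and 58 with dim genes left out. Of 31 list differences between subsets these held 0, 17, 21 and 21. With the replicate block 71 of the 78 calls and 29 of the 31 differences held, and 73 of the 78 calls held with each subset fitted alone. The cause was not tested where none is given. The planned Mo against PMN comparisons were not run. Where an array left out leaves 1 in its group, that array is assumed to vary like the other groups.

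Counts of genes that moved over 1.5 times were as follows. With each subset fitted alone they were 2 for Mo 3 weeks, 5584 for Mo 6 weeks and 877 for Mo 6 against 3 weeks. The PMN counts did not fall in that setting, at 14231 against 13047 for 6 weeks and 13248 against 11694 for 6 against 3 weeks. Fewer arrays alone therefore do not account for the lower Mo counts. The main fit uses 1 estimate of the spread of a gene for both subsets. With array weights, whose estimate did not converge, they were 15177, 14171 and 7809 in the same order, and 8561, 6840 and 11682 for the differences between subsets at 3 weeks, at 6 weeks and from 3 to 6 weeks. Quantile normalization gave 354 for Mo 3 weeks, 5241 for Mo 6 weeks and 15 for the difference at 3 weeks. The replicate block gave 2647 for Mo 3 weeks and 4 for that difference. Samples are taken to share only a number, since no label pairs them. Correlations of residuals between same-number arrays ran from -0.0895 to 0.628 over 9 Mo pairs and from -0.461 to 0.021 over 6 PMN pairs. The PMN pairs cannot show a pairing, because the residuals of the 2 arrays of a group mirror each other. In Mo, same-number pairs ran from 0.46 to 0.628 for replicates 1 and 3 and from -0.0895 to 0.284 for replicate 2. Pairs of replicate 1 with replicate 3 ran from -0.708 to -0.392. A pairing in Mo therefore stays open. In Mo, 7 of 9 arrays correlated best with their own number, a hint from the data and not the design. The floor gave 174 for Mo 3 weeks, 5403 for Mo 6 weeks, 9 for PMN 3 weeks, 6982 for PMN 6 weeks, 6344 for PMN 6 against 3 weeks and 8 for the difference at 3 weeks. Every feature gave 83 for Mo 3 weeks and 2 for that difference, leaving out dim genes gave 8 and averaged features 3. Median centring gave 7720 for PMN 6 against 3 weeks and 2260 for the difference at 6 weeks. A 2-fold minimum gave 26, 778 and 429 in Mo, 2007 and 1997 in PMN, and 903 and 1703 for the differences.

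Without 1 array in turn the counts ran from 16 to 8911 (Mo 3 weeks), 4475 to 10640 (Mo 6 weeks), 1000 to 2803 (Mo 6 against 3 weeks), 0 to 0 (PMN 3 weeks), 9383 to 12673 (PMN 6 weeks), 7627 to 9166 (PMN 6 against 3 weeks), and 0 to 3242, 2098 to 3683 and 3641 to 9334 for the differences. List calls ran from 73 to 83, and the correlation of 6-week responses from 0.654 to 0.71; it was 0.632 after quantile normalization and 0.598 with the floor.

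Nos2 in Mo from 3 to 6 weeks turned to 0.29 with array weights. In PMN at 3 weeks the camera direction of the mitosis list turned with the block, where its median was 0.144 against 0.029, and without 1 array the monocyte list ran from -0.155 to 0.11, the lysosome list from -0.192 to -0.011, the immediate early list from -0.197 to -0.006 and the B cell list from -0.261 to 0.195, with the camera direction turning. Signal over background limits genes near the lower end of the intensities, such as Arg1, whose change in PMN at 6 weeks was 0 with the floor.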

Other observations

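The test of olfactory and vomeronasal receptors was chosen after the result was seen; the counts over splits of the arrays were chosen before.

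In Mo cells at 6 weeks several members of the monocyte, lipid and lysosome lists moved apart, although these lists did not pass: the fractalkine receptor gene Cx3cr1 (-1.64), Adgre4 (-1.58), the receptor kinase gene Axl (-1.15) and the lipid scavenger receptor gene Cd36 (-1.28) fell, and the lysosomal protease genes Ctsl (1.40) and Ctsd (1.35) and the lipid genes Scd2 (1.75) and Acadl (1.48) rose. The transcription factor genes Myb (1.61) and Myc (1.22) and the transferrin receptor gene Tfrc (2.26) rose. In PMN cells at 6 weeks Myb (1.44), Tfrc (1.73), the granulocyte factor gene Cebpe (1.24), the Fc receptor gene Fcgr2b (1.36) and the leukotriene B4 receptor gene Ltb4r1 (2.15) rose, and the chemokine receptor gene Ccr7 fell by 1.00.

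Other lists did not pass camera from naive to 6 weeks. Progenitor markers had 3 of 15 higher and 5 lower in Mo (adjusted p = 0.781) and 3 and 8 in PMN (0.375), red pulp macrophage markers had 1 of 16 higher and 6 lower in Mo (0.119) and 1 and 1 in PMN (0.49), and basophil and mast cell markers had 1 of 13 higher and 3 lower in Mo (0.367) and 3 and 3 in PMN (0.883). Eosinophil markers had 1 of 8 lower in Mo (0.34) and 4 in PMN (0.459), and in PMN erythroid markers had 1 of 16 higher and 2 lower (0.516), platelet genes 2 of 11 higher and 5 lower (0.493), and dendritic cell markers 1 of 16 higher and 10 lower (0.0707).

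More genes were lower than higher in PMN cells at 6 weeks. A shift of dim features by background or normalization is a candidate explanation for the excess: olfactory and vomeronasal receptor genes, which blood cells do not use and which had a median level of 5.29, were lower past the threshold in 57.3% of 1194 cases (684 lower, 0 higher, median -0.36), against 40% of all tested genes. After median centring the shares were 27.5% and 17.6%. The shift does not reach the size of the large falls, such as Ptgs2 at -4.44. Lower counts of such receptors also stood in Mo at 6 weeks (593) and 3 weeks (13) and in PMN from 3 to 6 weeks (503), with 0 in PMN at 3 weeks. A lower output of many genes in the PMN cells at 6 weeks was not tested and stays open.

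The 6 arrays of each Mo comparison make 10 splits into 3 and 3, too few for a share under 0.05. From naive to 3 weeks 2 of the 10 splits gave as many genes as the real one (1202), and the highest other gave 6925; it set naive replicates 1 and 2 with 3-week replicate 1 against the rest, which points to a structure of these samples other than their stage. From naive to 6 weeks 1 split, the real one, gave as many as 9204, and the highest other gave 0. From 3 to 6 weeks 1 split, the real one, gave as many as 1497, and the highest other gave 1306.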
